A study of Homo sapiens with 9 samples.

How the data were processed

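The series measured RNA in MCF-7, an established line of estrogen receptor positive breast adenocarcinoma cells, in 9 libraries. Per the labels, 3 libraries came from untreated parental cells, 2 from cells kept in 500 nM abemaciclib, an inhibitor of the kinases CDK4 and CDK6, and 4 from cells kept in 100 nM fulvestrant, a degrader of the estrogen receptor, together with 500 nM abemaciclib. The combined treatment was sampled as 2 libraries at 8 months, with the ESR1 change Y537S at 3%, and 2 at 12 months, with Y537S at 30%. The 12-month libraries are given in the labels as technical replicates, all others as biological replicates. Per the labels' protocols, total RNA was extracted with a Qiagen RNeasy kit and libraries were prepared on a Hamilton NGS STAR robot.

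The deposited values were raw read counts per gene. Per the submitters' processing notes, the authors trimmed reads with Trim Galore, aligned them to hg38 with HISAT2 and made the counts with featureCounts. No version, annotation release or strand setting is recorded, so reads of overlapping genes, antisense partners and near-identical copies cannot be assigned with certainty. The table held 60671 genes, and its 9 columns were assigned to the libraries by their names. Gene symbols and identifiers were used as the table pairs them. Coordinates were taken from GENCODE on hg38 through stable gene identifiers, of which 58453 matched, including 18722 of the genes tested.

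Library depth was the sum of counts, from 10770362 to 14412094. A gene with no read can lie at up to 3 counts, which is 0.208 to 0.279 CPM depending on the library. Such floors, and the Poisson intervals given below, cover counting error only. CPM is the count divided by the library total and scaled to a common library size. Correlations between libraries used log2 of CPM plus 1, and pairs of libraries were compared over genes of at least 10 CPM on average. These correlations run across genes, which are not independent replicates.

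Differential expression was tested in R 4.3.3 with edgeR 4.0.16: low-count filtering by group, TMM normalization, robust quasi-likelihood fits with group as the only factor, and Benjamini-Hochberg adjustment over the 18988 genes tested, with a threshold of 0.05. Each adjusted p of a gene comes from this test unless another tool is named. Both 12-month libraries were summed, because technical replicates are not separate cultures, giving 8 libraries and 4 residual degrees of freedom. The 12-month arm was therefore 1 sample, assumed to vary like the other groups. The SE of a log2 change was its absolute value divided by the square root of the test's F statistic. It does not measure the spread between the summed 12-month libraries. The common biological coefficient of variation was 0.494. All 6 pairs of groups were compared, and the number of changed genes with a log2 change of at least 1 was also taken.

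The 32 gene lists, with 693 members, cover the cell cycle, DNA repair and damage responses, estrogen receptor and growth signalling, stress and metabolism, and markers of breast, stromal and blood cell types. They were written from textbook knowledge, together with the comparisons, tests, naming rule and most alternatives, before the data were examined. For each list, members past the threshold were counted over all genes tested and adjusted over the list alone. Lists were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, and again with an estimated correlation, with adjustment over lists within a comparison. A list's median is the median of its members' fitted log2 changes.

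Named genes followed a fixed rule. It took the 6 genes with the largest rise and the 6 with the largest fall among those that passed the test, reached a mean of 5 CPM in the higher group and separated the groups in every library, and up to 4 passing members of each list. Added to these were 25 fixed genes, changed or not: ESR1, TFF1, GREB1, PGR, CCND1, CCNE1, CCNE2, CDK2, CDK4, CDK6, RB1, CDKN1A, CDKN2C, E2F1, MKI67, ATR, CHEK1, WEE1, BRCA1, BRCA2, RAD51, FANCD2, EGFR, ERBB2 and MYC. Genes named outside this rule are marked as chosen after their values were seen. Mitochondrially encoded and replication-dependent histone genes were treated only as lists. XIST and Y-linked genes were left out of the text.

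Regional shifts were measured as the median log2 change of runs of 50 neighbouring tested genes, overlapping by 25. For each of 1000 random gene orders, the largest absolute deviation of a run median from the median of all genes was taken. The limit was the 95% quantile of these deviations. Calls shared between comparisons with the parental cells were set beside the number for independent lists. They were also set beside lists of the same lengths taken, by unadjusted p, from the top of 10 simulations of unchanged groups against the same controls, a reference chosen after the results were seen.

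The alternatives were DESeq2 size factors, no low-count filter, DESeq2 1.42.0, separate 12-month libraries, a block for replicate number, fits of only the groups compared, a 2-fold threshold, runs of 25 genes, an estimated correlation for the lists, and each library left out in turn. A pair of further fits was chosen after seeing the data. The first left out the library labelled 8 months, replicate 2, and both 12-month libraries. The other left out the library labelled 8 months, replicate 1, and 12-month replicate 2.

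The procedure was tested on simulated data. For the main fit, counts of the 18988 genes were drawn once, with the parental means, the real library sizes and the same dispersions in every group. For AbemaR against parental cells, 4.48%, 35.8% and 87.9% of genes with simulated log2 changes of 1, 2 and 4 were recovered, and 6 of 91 calls were false. At 8 months the shares were 1.49%, 25.4% and 92.4%, with 14 of 93 calls false, and at 12 months they were 2.99%, 13.4% and 75.8%, with 5 of 66 calls false. The simulated list had a camera adjusted p of 2.86e-43, while 1 of 30 other lists was called. With 60 neighbouring genes shifted, 2 runs were called, both overlapping them, and with no shift 0 runs were called. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.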

Results

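RNA was sequenced from 9 libraries of MCF-7 cells: untreated parental cells (n = 3), cells kept in abemaciclib (AbemaR, n = 2), and cells kept in fulvestrant and abemaciclib for 8 months (n = 2) or 12 months (2 technical replicates of 1 sample). The parental and AbemaR cells carried wild-type ESR1 per the labels, and Y537S was at 3% at 8 months and 30% at 12 months. The series asks about the responses to replication stress and DNA damage in cells resistant to these drugs. Total counts were 12345954, 14011463 and 10770362 in the parental libraries and 13710546 and 14412094 in the AbemaR libraries. They were 13033143 and 11804574 at 8 months and 11175456 and 13351301 at 12 months.

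The libraries did not all group as labelled. Pearson correlations across genes were 0.971 to 0.984 among the parental libraries and 0.953 between the AbemaR libraries, but only 0.883 between the 8-month libraries. AbemaR replicate 1 correlated at 0.96 to 0.968 with the parental libraries, above its 0.953 with AbemaR replicate 2. AbemaR replicate 2 and the library labelled 8 months, replicate 1, correlated at 0.975. The library labelled 8 months, replicate 2, correlated at 0.981 with 12-month replicate 1, above the 0.932 between both 12-month technical replicates. Of 10157 genes, 30.2% lay over 2-fold apart between the 8-month libraries, 21.7% between the AbemaR libraries and 16.8% between the 12-month libraries, against 4.8% to 14.6% in the parental pairs. Group comparisons below keep the labels, and counts of changed genes and of regional runs without the libraries that stand apart are given beside them.

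**Figure D1:**
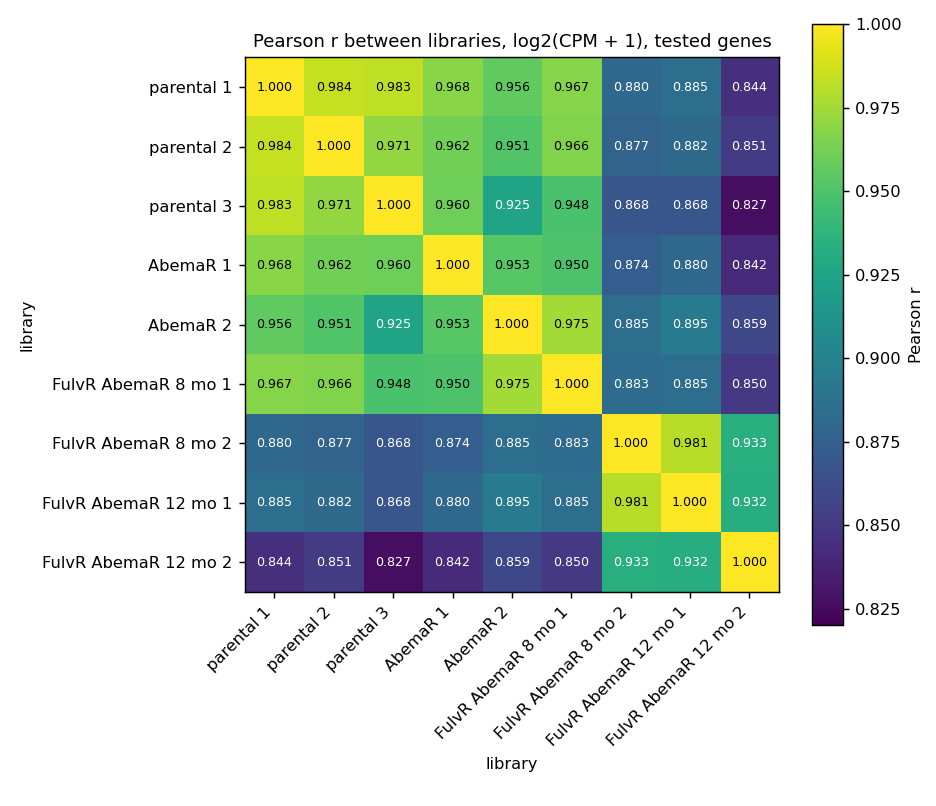
Pearson correlation across genes of log2(CPM + 1) for each pair of the 9 libraries, with the value in each cell. The library labelled 8 months, replicate 2, sits with the 12-month libraries (0.981 and 0.933) rather than with the other 8-month library (0.883).

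Some genes could not be assessed. All 13 mitochondrially encoded mRNAs had no read in any library, so their list had 0 members to test. In the major histocompatibility region of chromosome 6 (6p21), 118 of 139 protein-coding genes (84.9%) had no read, against 15.1% of the other genes of that chromosome. Only 7 members of the antigen presentation list were tested.

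AbemaR against parental cells asks what long-term abemaciclib left changed. Genes of DNA replication and cell division rose in the AbemaR cells. MKI67, a marker of proliferating cells (ENSG00000148773, chromosome 10, 128096659 to 128126385), was at 481 ± 175 CPM (SD, n = 2) against 46.2 ± 14 (n = 3), a log2 change of 3.41 ± 0.44 (SE; adjusted p = 0.0295). Of the 46 replication genes and E2F targets, 15 rose and none fell, led by UHRF1 (5.40 ± 0.64), MCM10 (5.37 ± 0.63), RRM2 (5.02 ± 0.78) and ORC1 (4.67 ± 0.78), and 42 rose when adjusted over the list alone. The list median was 1.97 (camera adjusted p = 4.73e-41, or adjusted p = 0.0692 with an estimated correlation). Of 40 mitosis genes, 24 rose, including CCNA2 (3.93), ESPL1 (3.93), DLGAP5 (3.90) and BIRC5 (3.78), and 38 rose when adjusted over the list alone. The median was 2.99 (adjusted p = 1.61e-45, or adjusted p = 0.129 with an estimated correlation). In the CDK-RB list E2F1 (3.53 ± 0.49) and E2F2 (4.98 ± 0.82), transcription factors that drive S-phase genes, rose among 24 members, while 9 rose and 1 fell when adjusted over the list alone. That list's median was 0.76 (adjusted p = 1.27e-05, or adjusted p = 0.129 with an estimated correlation). FAM111B (4.99 ± 0.58) was also among the largest rises.

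Of the DNA damage lists, those of the replication stress response, homologous recombination, the Fanconi anemia pathway and p53 targets passed in the same comparison. Whether these lists changed apart from the genes of DNA replication and cell division was not tested, here or in the later comparisons. Of 35 genes of the replication stress response, 6 rose, among them PKMYT1 (4.07 ± 0.51), a kinase that inhibits CDK1, BLM (3.64), CLSPN (3.54) and the checkpoint kinase CHEK1 (2.58 ± 0.41), and 9 rose when adjusted over the list alone (median 0.71; camera adjusted p = 7.6e-08, or adjusted p = 0.0587 with an estimated correlation). ATR did not pass, at −0.86 (adjusted p = 0.657). Of 30 homologous recombination genes, 4 rose: the nuclease gene EXO1 (4.40 ± 0.53), the recombinase gene RAD51 (4.21 ± 0.72), RAD51AP1 (3.50; adjusted p = 0.0495, or 0.0501 with DESeq2 size factors) and RMI1 (2.21). Adjusted over the list alone the count was 16 (median 1.15; adjusted p = 3.55e-12, or adjusted p = 0.0587 with an estimated correlation). BRCA1 (2.22, adjusted p = 0.0525) and BRCA2 (2.56, adjusted p = 0.0973) missed the threshold, with BRCA2 at 83.3 ± 3.25 CPM (n = 2) against 14.4 ± 2.13 (n = 3). Of 21 Fanconi anemia genes, FANCI (3.27), FANCD2 (2.5) and FANCA (2.25) rose, and 7 rose when adjusted over the list alone (median 0.56; adjusted p = 1.74e-05, or adjusted p = 0.0692 with an estimated correlation). NEIL3, a base excision glycosylase, rose by 4.04, 1 of 20 genes of its list. The base excision, end joining, mismatch repair, nucleotide excision, translesion synthesis and ATM checkpoint lists did not pass (camera adjusted p from 0.333 to 0.981, or adjusted p from 0.645 to 0.982 with an estimated correlation).

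No p53 target passed over all genes, but 9 of 27 fell when adjusted over the list alone, with a median of −1.17 (camera adjusted p = 3.55e-12, or adjusted p = 0.153 with an estimated correlation). CDKN1A, the p53 target encoding the CDK inhibitor p21, was at 140 ± 2.68 CPM (n = 2) against 609 ± 228 (n = 3), with a log2 change of −2.10 ± 0.46 and an adjusted p of 0.119. Of 33 type I interferon genes 0 passed over all genes and 10 rose when adjusted over the list alone (median 1.58; adjusted p = 3.03e-08, or adjusted p = 0.603 with an estimated correlation). Estrogen receptor targets had 0 of 40 members past the threshold and a median of 0.49 (adjusted p = 0.0384, or adjusted p = 0.645 with an estimated correlation), with TFF1 at −0.38, GREB1 at 0.29, PGR at −0.06 and ESR1 itself at 1.02. Immediate-early genes, which growth signals switch on within minutes, rose as a list (median 0.80; adjusted p = 0.0237, or adjusted p = 0.293 with an estimated correlation), with 0 of 14 over all genes and 5 adjusted over the list alone. Cholesterol biosynthesis genes also rose as a list (0.50; adjusted p = 0.0282, or adjusted p = 0.645 with an estimated correlation), with 0 of 24 by either count. Both falling genes were CPHL1P, a pseudogene (−4.06 ± 0.66), and the mucin gene MUC19 (−3.16 ± 0.52). RB1, the retinoblastoma gene, differed between the AbemaR libraries, at 4.38 and 43.9 CPM against 22.4 to 31.5 in the parental libraries.

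In all, 104 genes rose and 2 fell between AbemaR and parental cells, each by at least 2-fold, and 1573 had an unadjusted p under 0.05. DESeq2 called 313 higher and 104 lower. Among the 25 fixed genes 5 passed, and the other 20 ranged from −2.10 (CDKN1A) to 2.60 (CDK6). The calls ended when any parental library was left out, with smallest adjusted p of 0.0766, 0.283 and 0.218 without replicates 1, 2 and 3, and when AbemaR replicate 2 was left out (0.236). The estrogen receptor list lost its call without parental replicate 2 (adjusted p = 0.0637) or 3 (0.246) and without AbemaR replicate 2 (median 0.00, adjusted p = 0.963). It also lost its call with the 12-month libraries kept separate (0.0928) and with replicate number as a block (0.238), as did the cholesterol list with the block (0.0817). The immediate-early list lost its call without AbemaR replicate 2 (0.0968), and the cholesterol list lost its call without parental replicate 3 (0.123) and was at −0.08 without AbemaR replicate 2. Without AbemaR replicate 1 CHEK1, RAD51, RAD51AP1, FANCA, RMI1, CPHL1P and MUC19 missed the threshold (adjusted p from 0.0514 to 0.185), and MUC19 also missed it without 12-month replicate 2 (0.121) and with the 12-month libraries kept separate (0.642). BRCA1, BRCA2 and CDKN1A passed without 8-month replicate 1 or 2 (adjusted p from 0.00529 to 0.0349). Without the library labelled 8 months, replicate 2, and both 12-month libraries, 229 rose and 39 fell, including all 106 of the first calls, and BRCA1, BRCA2 (both higher) and CDKN1A (lower) passed with adjusted p of 0.00991, 0.00584 and 0.037.

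**Figure D2:**
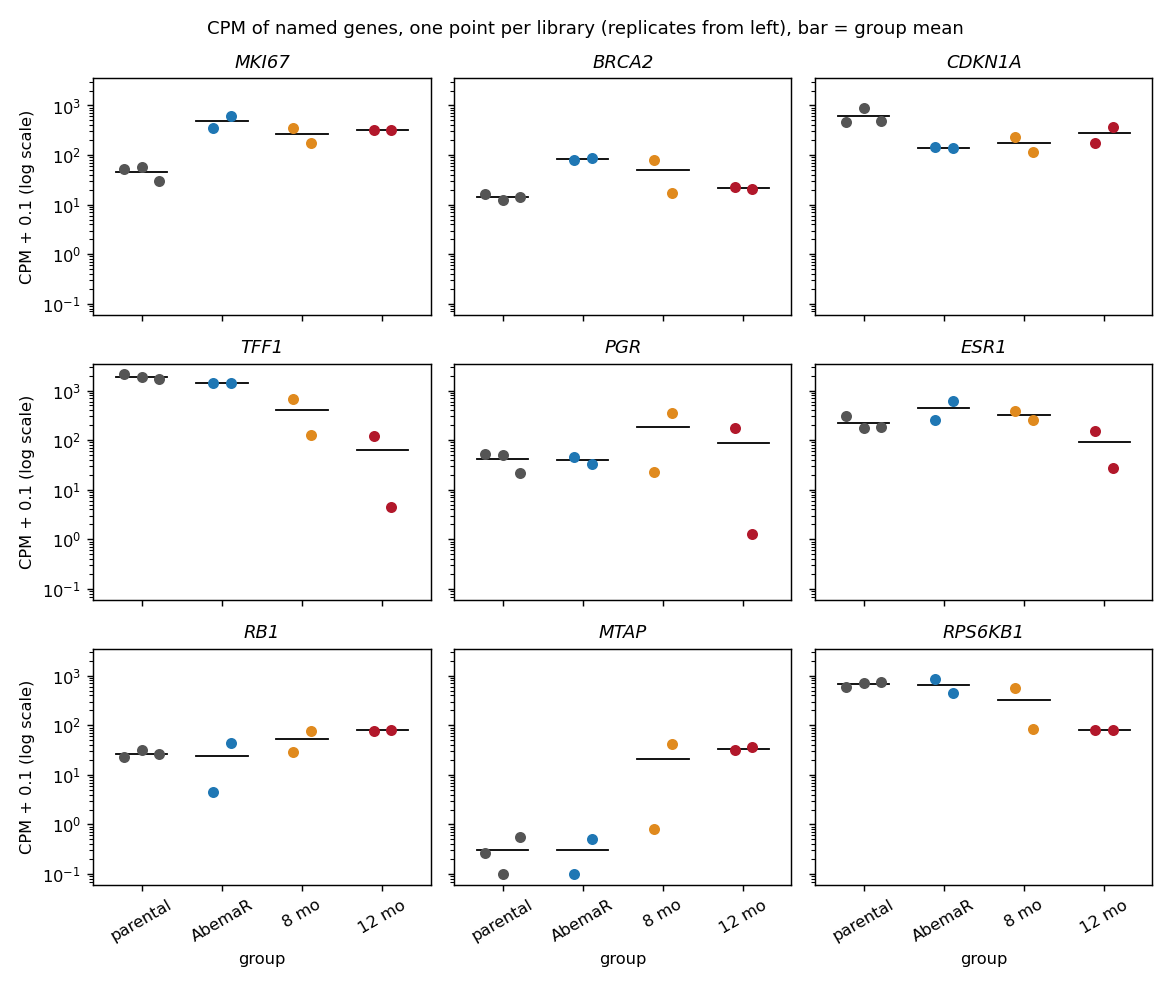
CPM plus 0.1 of 9 genes in each of the 9 libraries on a shared log axis, with points for libraries and bars for group means. MKI67 lies between 30.2 and 56.0 CPM in the parental libraries and between 178 and 605 in all 6 treated libraries, while MTAP and RPS6KB1, chosen after their values were seen, separate 3 libraries from the other 6.

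At 8 months of combined treatment, the comparison with parental cells asks what fulvestrant and abemaciclib together left changed. By edgeR 0 genes passed in either direction, so the values here describe levels and lists. MKI67 was at 263 ± 120 CPM (n = 2) against 46.2 ± 14 (n = 3), a log2 change of 2.43 ± 0.43 (adjusted p = 0.0985). RAD51 (4.09) and E2F1 (2.73) had the same adjusted p, FANCD2 was at 2.25 (adjusted p = 0.106), and CDKN1A at −1.89 (adjusted p = 0.154). BRCA2, at 1.67 for the group, was at 80.3 CPM in replicate 1 and 17.3 in replicate 2, against 12.3 to 16.6 in the parental libraries. TFF1, an estrogen receptor target, was at 402 ± 387 CPM against 1890 ± 227 (−2.33 ± 0.62, adjusted p = 0.18), while ESR1 was at 0.50 and PGR at 2.19.

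As lists, the mitosis genes rose at 8 months with a median of 2.64 (camera adjusted p = 4.02e-28, or adjusted p = 0.28 with an estimated correlation), and 37 of 40 rose when adjusted over the list alone. The replication list rose by a median of 0.86 (adjusted p = 1.05e-11; 20 of 46 adjusted over the list alone), and the CDK-RB list by 0.95 (adjusted p = 0.00357; 6 up and 1 down of 24 adjusted over the list alone). Each had an adjusted p = 0.28 with an estimated correlation. The replication stress list rose by 0.36 (adjusted p = 0.00442; 7 of 35 adjusted over the list alone) and the homologous recombination list by 0.97 (adjusted p = 6.89e-04; 13 of 30 adjusted over the list alone). Both had an adjusted p = 0.28 with an estimated correlation. The Fanconi anemia list did not pass (median 0.01, adjusted p = 0.1, or adjusted p = 0.289 with an estimated correlation; 4 of 21 adjusted over the list alone), nor did the other 6 repair and checkpoint lists (adjusted p from 0.53 to 0.994, or adjusted p from 0.667 to 0.995 with an estimated correlation). Type I interferon genes had a median of 3.47, and 26 of 33 rose when adjusted over the list alone (adjusted p = 4.72e-16, or adjusted p = 0.28 with an estimated correlation). The p53 targets fell, with a median of −1.22 (adjusted p = 6.51e-10, or adjusted p = 0.28 with an estimated correlation; 14 of 27 lower adjusted over the list alone). Immediate-early genes rose as a list (median 0.87; adjusted p = 0.0243, or adjusted p = 0.28 with an estimated correlation; 7 of 14 adjusted over the list alone). Replication-dependent histone genes rose as a list (0.98; adjusted p = 0.0143, or adjusted p = 0.534 with an estimated correlation; 0 of 20 adjusted over the list alone), and cholesterol biosynthesis genes fell (−0.36; adjusted p = 0.00445, or adjusted p = 0.552 with an estimated correlation; 1 of 24 lower adjusted over the list alone). All 24 genes of the integrated stress and unfolded protein response were negative, with a median of −1.11 (adjusted p = 2.53e-06, or adjusted p = 0.501 with an estimated correlation), 0 of them lower when adjusted over the list alone. Estrogen receptor targets had a median of 0.53 (adjusted p = 0.806, or adjusted p = 0.932 with an estimated correlation). The library medians of the interferon list, as differences in log2(CPM + 1) from the parental mean, were 2.52 and 0.84 in replicates 1 and 2. The added 1 shrinks changes of genes at low counts, so these medians are not on the scale of the fitted 3.47.

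The 0 calls at 8 months stood beside 2944 genes with an unadjusted p under 0.05 and DESeq2 counts of 768 higher and 232 lower. All 25 fixed genes missed the threshold, from −2.33 (TFF1) to 4.09 (RAD51). Leaving out the library labelled 8 months, replicate 1, gave 1941 higher and 1026 lower, with the remaining library as the whole arm, whereas leaving out replicate 2 gave 0 and 0. Without replicate 1 RAD51 (adjusted p = 7.38e-04), E2F1 (0.00102), FANCD2 (0.00714) and MKI67 (0.0155) passed as higher, and TFF1 (−3.84, 0.00169) and CDKN1A (0.0173) as lower. Without replicate 1 the replication stress, homologous recombination and CDK-RB lists lost their calls (adjusted p = 0.17, 0.162 and 0.0702), as did the immediate-early, histone and cholesterol lists (0.586, 0.17 and 0.0702). The immediate-early and histone calls also ended without parental replicate 3 (0.0643 and 0.0717) and with replicate number as a block (0.0723 and 0.057), and the former with no filter on low counts (0.0614). The Fanconi anemia list passed with the 12-month libraries kept separate (0.0417) and with only the groups compared (0.0293). Without replicate 2 the Fanconi anemia list gained one (adjusted p = 0.0412) and PGR turned to −1.01, having passed at 3.12 without replicate 1 (adjusted p = 0.00169).

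At 12 months, mitosis and replication genes again rose against parental cells. Of 40 mitosis genes, 24 rose, with ESPL1 at 4.54, the centromere gene CENPF at 4.50, HJURP at 4.27 and the survivin gene BIRC5 at 4.17 (median 3.01; camera adjusted p = 1.79e-18, or adjusted p = 0.472 with an estimated correlation; 38 adjusted over the list alone). Of 46 replication genes, 8 rose, including RRM2 (5.76 ± 0.85), CDC45 (5.12), MCM10 (4.84) and TK1 (4.40), and 21 rose when adjusted over the list alone (median 1.25; adjusted p = 1.65e-07, or adjusted p = 0.472 with an estimated correlation). MKI67 was at 323 and 324 CPM in the 12-month libraries (2.88 ± 0.49, adjusted p = 0.0386). In the CDK-RB list E2F2 (5.88), E2F1 (3.78) and CDC25A (3.66) rose among 24 (median 1.08; adjusted p = 0.0448, or adjusted p = 0.472 with an estimated correlation; 3 adjusted over the list alone).

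Of the DNA repair and checkpoint lists, that of the replication stress response passed at 12 months. In the replication stress list PKMYT1 (3.36), CLSPN (3.06) and EME1 (2.67) rose among 35 (median 0.66; camera adjusted p = 0.0448, or adjusted p = 0.472 with an estimated correlation), and 8 rose when adjusted over the list alone. EXO1 (5.20 ± 0.59), RAD51 (5.04 ± 0.80) and RAD51AP1 (4.54) rose among 30 homologous recombination genes, with 8 up and 2 down adjusted over the list alone (median 0.67; adjusted p = 0.135, or adjusted p = 0.5 with an estimated correlation). BRCA2 did not pass, at 0.66 (adjusted p = 0.549). FANCI (3.01) and FANCD2 (2.59) rose among 21 Fanconi anemia genes (6 adjusted over the list alone; median 0.51; adjusted p = 0.135, or adjusted p = 0.472 with an estimated correlation), and NEIL3 rose by 3.6. The translesion synthesis list, 8 genes, was at a median of −0.77 (adjusted p = 0.601, or adjusted p = 0.872 with an estimated correlation). The base excision, end joining, mismatch repair, nucleotide excision and ATM checkpoint lists did not pass either (adjusted p from 0.264 to 0.938, or adjusted p from 0.5 to 0.979 with an estimated correlation).

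Immediate-early genes, called higher by camera in AbemaR and at 8 months, did not pass as a list at 12 months but had 3 of 14 members past the threshold: EGR1 at 597 ± 31.9 CPM (2 technical replicates) against 53.8 ± 7.92 (n = 3; 3.55 ± 0.68), FOSB (2.78) and ZFP36 (2.52). FOSB was at 324 CPM in replicate 1 and 36.8 in replicate 2, against 22.1 to 32.2 in the parental libraries. The list's library medians, as differences in log2(CPM + 1) from the parental mean, were 1.61 and 0.25 in replicates 1 and 2. Adjusted over the list alone 7 rose (median 1.15; camera adjusted p = 0.0974, or adjusted p = 0.472 with an estimated correlation). The efflux pump gene ABCC2 rose by 3.28 and RAPGEFL1, of the estrogen receptor target list, by 3.30. That list had 5 members up and 6 down adjusted over the list alone (median −0.60; adjusted p = 0.35, or adjusted p = 0.949 with an estimated correlation), and TFF1 was at −4.93 ± 0.99 (adjusted p = 0.0534), ESR1 at −1.29, GREB1 at −1.01 and PGR at 1.06. In 12-month replicate 2 GREB1 was at 4.57 CPM and PGR at 1.20, against 644 and 176 in replicate 1. Interferon genes rose as a list (10 of 33 adjusted over the list alone; median 1.94; adjusted p = 2.54e-05, or adjusted p = 0.72 with an estimated correlation). The p53 targets fell as a list (median −1.03; adjusted p = 3.05e-05, or adjusted p = 0.472 with an estimated correlation), with 0 of 27 adjusted over the list alone.

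The 6 largest rises at 12 months were all highest in replicate 2. LMO3 was at 872 CPM in replicate 2 and 3.94 in replicate 1, with a log2 change of 10.22. CP, RHBDL3, TNFSF10, SPINK8 and SLC12A1 had at most 3 reads in each parental library, so no fold is given. CP was at 145 and 1.07 CPM in replicates 2 and 1, RHBDL3 at 142 and 11.5, TNFSF10 at 103 and 8.77, SPINK8 at 176 and 8.59, and SLC12A1 at 145 and 0.716.

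At 12 months 231 genes rose and 0 fell by edgeR, each rise at least 2-fold, with 4569 genes at an unadjusted p under 0.05 and DESeq2 counts of 1239 higher and 934 lower. Among the 25 fixed genes 4 passed, and the other 21 ranged from −4.93 (TFF1) to 2.68 (CDK6). The calls ended without parental replicate 1, 2 or 3 (smallest adjusted p of 0.0542, 0.162 and 0.0837), and fell to 128 higher and 2 lower without AbemaR replicate 1 and to 107 and 2 without AbemaR replicate 2. They rose to 2440 and 1133 without 8-month replicate 1, to 2349 and 1147 without 8-month replicate 2 and to 824 and 220 without 12-month replicate 1. Without 12-month replicate 2 there were 89 higher and 0 lower, 79 of them among the 231. TFF1 passed, as lower, without 8-month replicate 1 or 2 (adjusted p = 5.14e-04 and 6.28e-04) and without 12-month replicate 1 (−8.70, adjusted p = 0.0132), and CDK6 passed, as higher, without 8-month replicate 1 or 2 (0.0464 and 0.0467). Without 12-month replicate 2 LMO3 (adjusted p = 0.198), ABCC2 (0.114), CDC25A (0.1), CLSPN (0.0956), EGR1 (0.0705), EME1 (0.0533) and E2F2 (0.0504) missed the threshold, as did CP (0.163), RHBDL3 (0.089), TNFSF10 (0.11), SPINK8 (0.116) and SLC12A1 (0.193). Without AbemaR replicate 1 or 2 MKI67, CDC25A, NEIL3, EME1, RAPGEFL1, ZFP36, RHBDL3, TNFSF10 and SPINK8 missed it (adjusted p up to 0.0666), and without AbemaR replicate 2 CLSPN and CDC45 did too. Without 12-month replicate 1 FOSB (0.57, adjusted p = 0.511), ZFP36 (1.83, 0.0639) and RAPGEFL1 (1.98, 0.101) missed it, while ESR1 (−2.93, 0.0456) and GREB1 (−7.04, 0.0147) passed as lower. Without replicate 1 the interferon list lost its call (median 0.43, adjusted p = 0.241) and the estrogen receptor targets fell (median −2.61, adjusted p = 1.05e-06), while without replicate 2 their median was 0.35. Without replicate 2 the homologous recombination and immediate-early lists passed (adjusted p = 0.0352 and 0.00101), the latter also without AbemaR replicate 1 or 2 (0.0346 and 0.0341), whereas without 12-month replicate 1 the immediate-early median was 0.30. The homologous recombination list also passed with replicate number as a block (0.0408), and the Fanconi anemia list with the 12-month libraries kept separate (0.0414). The replication stress and CDK-RB lists lost their calls without parental replicate 2 or 3, 8-month replicate 1 or 2, or 12-month replicate 1 (adjusted p from 0.0503 to 0.123). Both calls also ended with no filter on low counts (0.0984 and 0.106) and with only the groups compared (0.0897 and 0.0654).

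**Figure D3:**
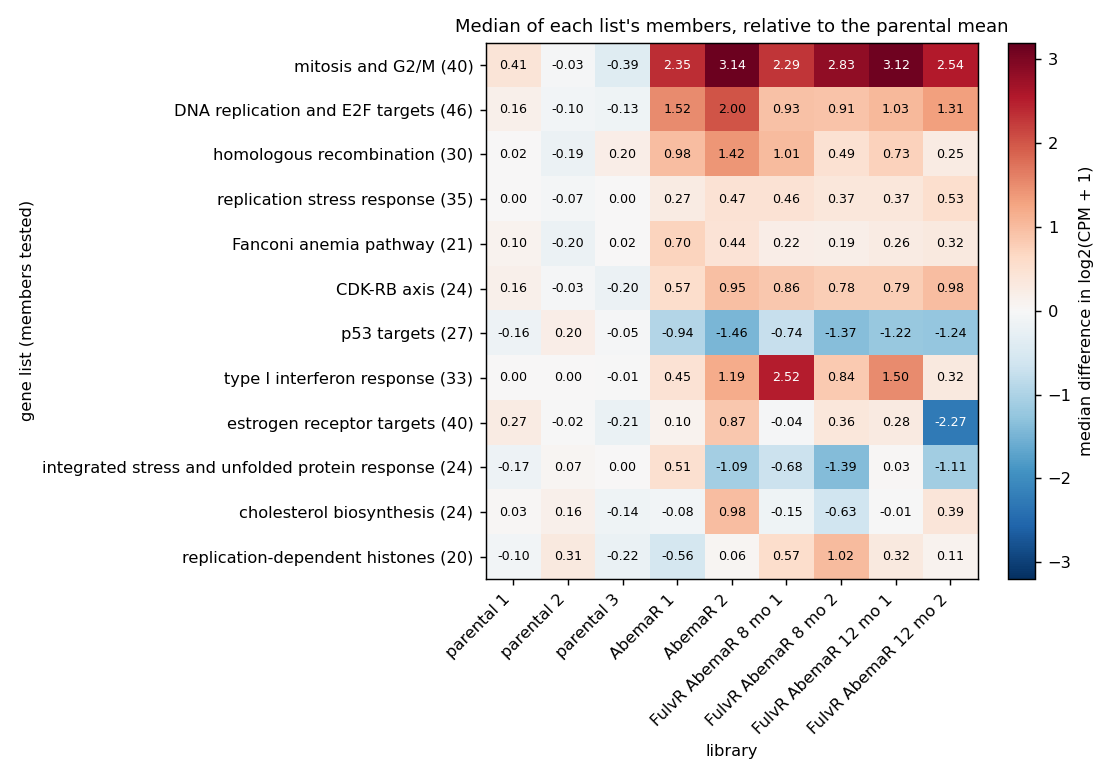
Median difference in log2(CPM + 1) from the parental mean for the members of 12 gene lists in each of the 9 libraries. The mitosis list is at 2.29 to 3.14 in all 6 treated libraries, and the estrogen receptor targets are at −2.27 in 12-month replicate 2 and between −0.04 and 0.87 in the other treated libraries.

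Combined treatment at 8 months against AbemaR sets both drugs beside abemaciclib alone. The labels give no treatment time for AbemaR, which carried wild-type ESR1, while Y537S was at 3% at 8 months. An effect of fulvestrant therefore cannot be told apart here from one of time or ESR1 genotype. Replication genes fell as a list: all 46 were lower, with a median of −0.92 (camera adjusted p = 1.3e-12, or adjusted p = 0.359 with an estimated correlation), and 4 fell when adjusted over the list alone. The homologous recombination list fell (median −0.49; adjusted p = 0.00161, or adjusted p = 0.359 with an estimated correlation) with 0 of 30 adjusted over the list alone. The replication stress list (−0.24; adjusted p = 0.0325) and the Fanconi anemia list (−0.32; adjusted p = 0.0281) fell too, each with an adjusted p = 0.359 with an estimated correlation and 0 members adjusted over the list alone. The mitosis list fell by a median of −0.42 (adjusted p = 0.0105, or adjusted p = 0.82 with an estimated correlation; 0 of 40 adjusted over the list alone). Fibroblast markers, 6 genes, fell as a list (−1.07; adjusted p = 0.0281, or adjusted p = 0.359 with an estimated correlation; 0 adjusted over the list alone). All 33 interferon genes were higher, with a median of 1.48 (adjusted p = 2.89e-06, or adjusted p = 0.625 with an estimated correlation), 0 of them when adjusted over the list alone. Cholesterol biosynthesis genes fell (median −0.95, 4 of 24 adjusted over the list alone; adjusted p = 1.46e-06, or adjusted p = 0.394 with an estimated correlation), as did the integrated stress list (−1.09; adjusted p = 6.11e-04, or adjusted p = 0.676 with an estimated correlation; 0 of 24 adjusted over the list alone). Replication-dependent histone genes rose as a list (1.53, 5 up and 1 down of 20 adjusted over the list alone; adjusted p = 2.06e-05, or adjusted p = 0.392 with an estimated correlation). TFF1 was at −1.95 (adjusted p = 0.439) and PGR at 2.24, the ends of the range of the 25 fixed genes, none of which passed.

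By edgeR 0 genes passed between 8 months and AbemaR, with 1944 at an unadjusted p under 0.05 and DESeq2 counts of 277 higher and 113 lower. Without 8-month replicate 1, edgeR gave 1194 higher and 762 lower, and the interferon list lost its call (median 0.10, adjusted p = 0.937). TFF1 (−3.45, adjusted p = 0.00446), BRCA2 (−2.25, 0.0155) and PGR (3.19, 0.00455) then passed, and without replicate 2 PGR was at −0.95. Without 8-month replicate 2 the integrated stress list lost its call (adjusted p = 0.0583), without AbemaR replicate 1 its median was 0.31, and without AbemaR replicate 2 the homologous recombination and cholesterol lists lost theirs (adjusted p = 0.11 and 0.0932). The replication stress, Fanconi anemia and fibroblast lists lost their calls without AbemaR replicate 2 (0.348, 0.223 and 0.384) or 8-month replicate 1 (0.368, 0.295 and 0.0886), and the fibroblast list also without 8-month replicate 2 (0.119). The fibroblast call ended with no filter on low counts (0.131) and with the 12-month libraries kept separate (0.0593), and the Fanconi anemia call with only the groups compared (0.0598). The mitosis list lost its call without 8-month replicate 1 (0.687) and was at 0.10 without AbemaR replicate 2.

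The comparison of 12 with 8 months spans the rise in the labelled Y537S share from 3% to 30%. In it LINC00578, a long non-coding RNA, rose by 7.31 ± 0.68 (adjusted p = 0.0241), with 324 CPM in 12-month replicate 2, 1.79 in replicate 1 and 0.614 and 1.78 at 8 months. LHX9, encoding a homeobox factor, and MUC19 were the other rising genes and were named after their values were seen. LHX9 was at 549 and 0 CPM in 12-month replicates 2 and 1, and MUC19 at 342 and 1.70 (5.90, adjusted p = 0.0241). As a list, the estrogen receptor targets fell (median −0.71; camera adjusted p = 0.039) and cholesterol biosynthesis rose (0.74; adjusted p = 2.38e-04), both with an adjusted p = 0.797 with an estimated correlation. The interferon genes (−0.80) and replication-dependent histone genes (−0.96) fell, and the mitosis (0.49) and integrated stress (0.52) lists rose. These 4 lists had a camera adjusted p = 0.039, or adjusted p = 0.797 with an estimated correlation. All 6 lists had 0 members when adjusted over the list alone.

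Between 12 and 8 months 3 genes rose and 0 fell by edgeR, with 1029 at an unadjusted p under 0.05 and DESeq2 counts of 57 higher and 35 lower. The 25 fixed genes all missed the threshold, from −2.59 (TFF1) to 1.05 (E2F1). With each library left out in turn TFF1 ranged from −6.36 to −1.09, and it passed without 8-month replicate 2 (−3.32, adjusted p = 0.011). The calls ended without any parental or AbemaR library and without 12-month replicate 2, where LINC00578 was at 0.70, MUC19 at −0.85 and the estrogen receptor list at 0.02 (adjusted p = 0.349). That list's call also ended without parental replicate 2 (0.0549) or 8-month replicate 2 (0.823), and without 12-month replicate 1 its median was −2.05. The interferon list lost its call without 12-month replicate 2 (0.823) and turned to 0.14 without 8-month replicate 1. Without both 8-month replicate 1 and 12-month replicate 2 the interferon list rose (median 0.73, adjusted p = 4.24e-06). MUC19 missed the threshold without 8-month replicate 1 (0.0503), and the cholesterol list lost its call without 8-month replicate 2 (0.168). The mitosis call ended without parental replicate 2, 8-month replicate 1 or 2, or 12-month replicate 1 (adjusted p from 0.0613 to 0.591). The integrated stress call ended without 8-month replicate 2 (0.835) or 12-month replicate 1 (median −0.05, 0.991), and the histone call without 8-month replicate 2 (0.572) or 12-month replicate 2 (0.182). With no filter on low counts all of these calls but that of the cholesterol list ended (adjusted p from 0.0632 to 0.227), and the integrated stress call also ended with the 12-month libraries kept separate (0.0636) and with replicate number as a block (0.078). There were 642 higher and 478 lower without 8-month replicate 2, and 13 higher and 20 lower without 12-month replicate 1.

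Against AbemaR, the 12-month cells had lower replication genes as a list (median −0.67; camera adjusted p = 0.0039, or adjusted p = 0.997 with an estimated correlation), with 0 of 46 when adjusted over the list alone. Homologous recombination genes did not pass (−0.60; adjusted p = 0.0531, or adjusted p = 0.997 with an estimated correlation; 0 of 30 adjusted over the list alone). LINC00578 (9.29 ± 0.75, adjusted p = 0.00665), MUC19 (7.87 ± 0.66, adjusted p = 0.00665), the kidney cotransporter gene SLC12A1 (adjusted p = 0.04) and LHX9 (adjusted p = 0.0235) rose, LHX9 being named after its values were seen. The rises lay in 12-month replicate 2. TFF1 was at −4.54 (adjusted p = 0.213), the lowest of the 25 fixed genes, none of which passed.

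For 12 months against AbemaR 4 genes rose and 0 fell by edgeR, 3348 had an unadjusted p under 0.05, and DESeq2 gave 612 higher and 539 lower. No gene passed without parental replicate 2, without AbemaR replicate 1 or 2, or without 12-month replicate 2, and 2 rose without parental replicate 1 or 3. There were 1409 higher and 724 lower without 8-month replicate 1, 1311 and 752 without 8-month replicate 2, and 68 and 53 without 12-month replicate 1. TFF1 passed without 8-month replicate 1 or 2 (adjusted p = 0.00122 and 0.00141) and without 12-month replicate 1 (−8.32, 0.0228), and was at −3.44 without 12-month replicate 2. BRCA2, at −1.90, passed without 8-month replicate 1 or 2 (0.0262 and 0.0231). The replication list lost its call without AbemaR replicate 2 (median −0.34, adjusted p = 0.326), and the homologous recombination list gained one without AbemaR replicate 1 (adjusted p = 0.0107) and with no filter on low counts (0.0046).

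Markers of other cell types gave 0 members past the threshold over all genes in any comparison by edgeR: the fibroblast list had 6 tested members, the leukocyte list 4, the endothelial list 3 and the basal and myoepithelial list 12. Adjusted over the list alone, fibroblast markers had 2 up and 1 down at 12 months against parental cells and against AbemaR, and 2 up against 8 months. Endothelial markers had 2 up and 1 down at 12 months against parental cells and 1 down against AbemaR, and the other lists had 0. By camera only the fibroblast list was called, as lower at 8 months against AbemaR (adjusted p = 0.0281, or adjusted p = 0.359 with an estimated correlation).

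Calls were shared between treatments. The AbemaR and 12-month comparisons with the parental cells shared 65 rising genes of 104 and 231, where independent lists would share 1.27. Lists of the same lengths, taken from the top of 10 simulations of unchanged groups against the same controls, shared 16 to 28 (mean 23.4). These simulations drew every group, the parental one included, with the dispersions of the main fit (common biological coefficient of variation 0.494). Real parental pairs had 0.224 to 0.324 over genes of at least 10 CPM. The simulated sharing, covariances and correlations may therefore be too high, and they are no firm measure of what shared controls give. The covariance of log2 changes across 10157 genes was 0.28 between AbemaR and 8 months (simulated 0.127) and 0.333 between AbemaR and 12 months (simulated 0.13). Between 8 and 12 months it was 1.55 (simulated 0.132). The differences were 0.153, 0.202 and 1.42. The correlations across these genes, which are not independent replicates, were 0.326 between AbemaR and 8 months (simulated 0.387) and 0.262 between AbemaR and 12 months (simulated 0.31), both below the simulated values. Between 8 and 12 months the correlation was 0.834 (simulated 0.313). The same sign was found for 64.1%, 62.2% and 81.9% of genes, against 62.7%, 60.1% and 60.1% in the simulations. With 0 calls at 8 months, 0 genes changed in opposite directions at both time points.

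Shifts of neighbouring genes were counted for the labelled groups, although the 8-month group joins unlike libraries. Against parental cells, 0 of 717 overlapping runs of 50 genes lay beyond the limit of random orders in AbemaR, 37 at 8 months (24 higher, 13 lower) and 67 at 12 months (39 higher, 28 lower). At 8 months there were 66 such runs without replicate 1 and 19 without replicate 2 (6 higher, 13 lower), so that the count differed between these libraries. When each library was left out in turn there were 0 to 6 in AbemaR and 63 to 72 at 12 months. On chromosome 1, the run from 220094102 to 226739323 (hg38) had a median of 1.42 at 8 months and 2.12 at 12 months. On chromosome 17, the run from 58631641 to 63427699, which holds RPS6KB1 (ENSG00000108443, 59893046 to 59950564), had a median of −1.63 at 12 months. RPS6KB1, encoding a ribosomal S6 kinase and named after its values were seen, was at 80.2 to 82.8 CPM in the library labelled 8 months, replicate 2, and both 12-month libraries, against 453 to 863 in the other 6. The lowest 12-month run, at −2.87, held the protocadherin clusters of chromosome 5 (140821604 to 141512979), whose overlapping genes share exons and whose counts are uncertain. There were 44 runs beyond the limit for 8 months against AbemaR, 64 for 12 against 8 months and 77 for 12 months against AbemaR. Without 8-month replicate 1 these were 66, 21 and 81, and without 8-month replicate 2 they were 17, 70 and 80. For 8 months against AbemaR there were 29 without AbemaR replicate 1 and 17 without AbemaR replicate 2.

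**Figure D4:**
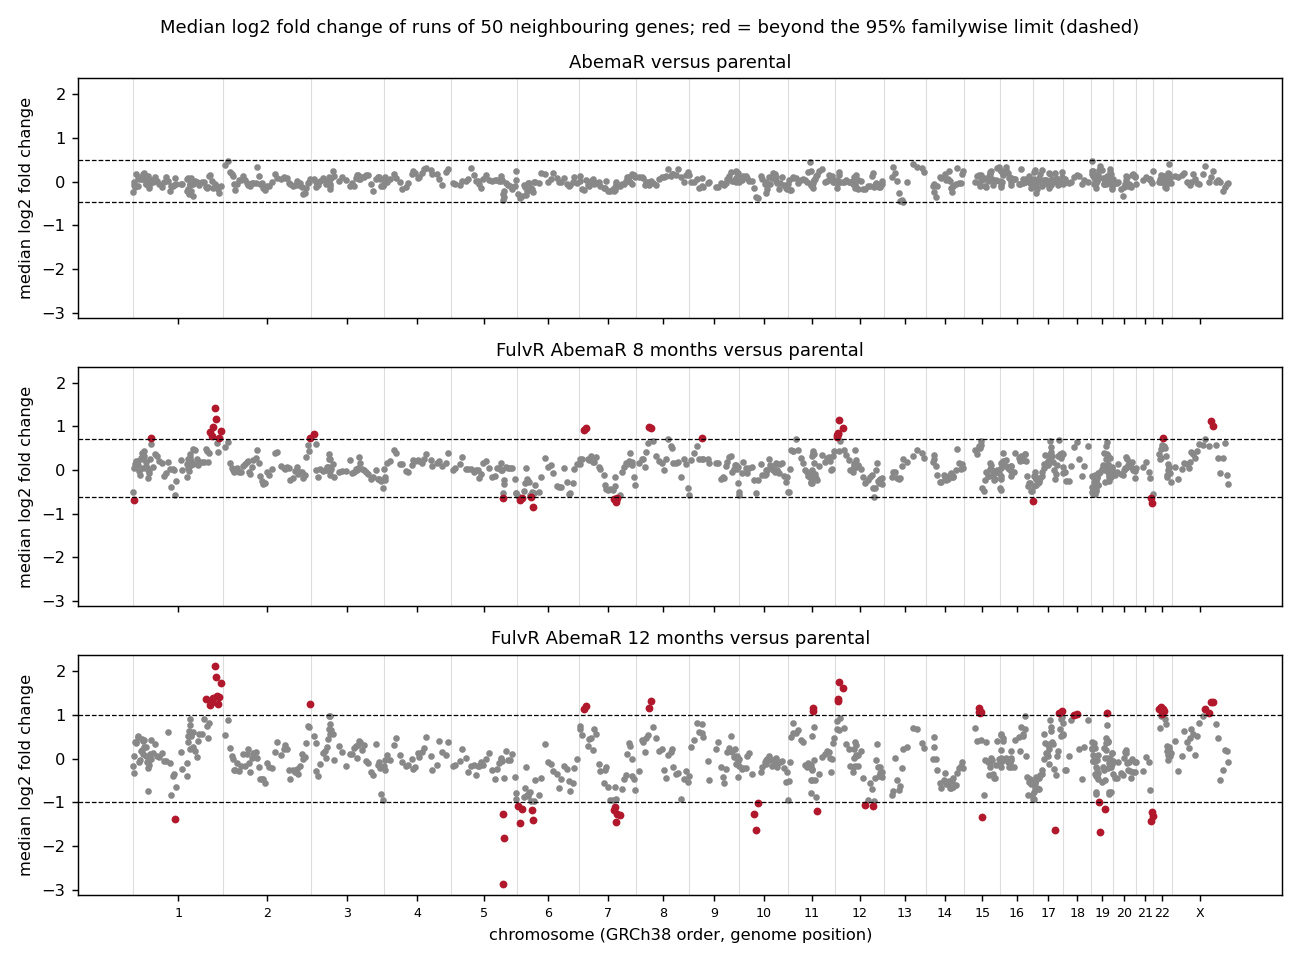
Median log2 change against parental cells of overlapping runs of 50 neighbouring genes along the chromosomes, for AbemaR, 8 months and 12 months, with runs beyond the limit of random orders in red. There are 0, 37 and 67 such runs.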

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

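The tests that left out more than 1 library, and all regional counts with libraries left out, were chosen only after the results were seen, and all other alternatives were planned. Of 107 named gene results and 53 list results, most kept their direction and their side of the threshold: 1286 alternative gene values and 728 list values did, 357 and 126 no longer passed, 91 and 14 newly passed, and 22 and 14 changed direction. DESeq2 size factors ended the call of 1 named gene (RAD51AP1 in AbemaR, adjusted p = 0.0501), and 0 counts moved by over 1.5 times under them. The cause of the changes was not tested. Fewer samples leave fewer degrees of freedom, which alone would lower the counts. Yet several counts rose when either 8-month library was left out. The biological coefficient of variation was 0.591 between the 8-month libraries, against 0.41 between the AbemaR libraries. Leaving out either 8-month library removes that spread from the fit shared by all groups. Whether this raised the counts was not tested. A lone library left as a group is assumed to vary like the other groups. Depth limits genes near the floor of 3 counts, and at this size most simulated log2 changes of 2 were missed.

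Counts are given as higher and lower, in the order AbemaR, 8 months and 12 months against parental cells, 8 months against AbemaR, 12 against 8 months, and 12 months against AbemaR. The main counts were 104 and 2, 0 and 0, 231 and 0, 0 and 0, 3 and 0, and 4 and 0. With no filter on low counts they were 363 and 95, 1245 and 297, 2147 and 786, 531 and 189, 134 and 140, and 1233 and 572. By DESeq2 they were 313 and 104, 768 and 232, 1239 and 934, 277 and 113, 57 and 35, and 612 and 539. With the 12-month libraries kept separate they were 131 and 2, 0 and 0, 1442 and 819, 0 and 0, 0 and 0, and 0 and 0. With only the groups compared they were 221 and 34, 0 and 0, 3186 and 2086, 0 and 0, 0 and 0, and 1258 and 606. Without the libraries labelled 8 months, replicate 1, and 12 months, replicate 2, they were 225 and 40, 1876 and 1039, 1837 and 897, 1122 and 774, 0 and 0, and 1037 and 583. Without the library labelled 8 months, replicate 2, and both 12-month libraries they were 229 and 39 for AbemaR against parental cells and 0 and 0 for both 8-month comparisons, and comparisons with 12 months had no value.

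Leaving out each of the 9 libraries in turn gave 0 to 239 higher and 0 to 45 lower for AbemaR, 0 to 1941 and 0 to 1026 for 8 months, and 0 to 2440 and 0 to 1147 for 12 months, each against parental cells. It gave 0 to 1194 and 0 to 762 for 8 months against AbemaR, 0 to 642 and 0 to 478 for 12 against 8 months, and 0 to 1409 and 0 to 752 for 12 months against AbemaR. The camera calls, 45 over all comparisons, ranged from 30 to 52, and 0 remained with an estimated correlation. The rising genes shared by AbemaR and 12 months, 65 at first, ranged from 0 to 185. They were 254 with no filter, 204 by DESeq2, 118 with the 12-month libraries separate, 175 with only the groups compared, and 176 without the libraries labelled 8 months, replicate 1, and 12 months, replicate 2. Genes with opposite effects at both time points ranged from 0 to 1, the 1 without 8-month replicate 1. With runs of 25 genes, the regional counts went from 37 to 14, 67 to 40, 44 to 13, 64 to 31 and 77 to 40 in the order above from 8 months against parental cells on, and stayed at 0 for AbemaR. With each library left out in turn they ranged from 0 to 6 for AbemaR, then in that order from 19 to 66, 63 to 72, 17 to 66, 21 to 70 and 62 to 81. Without the libraries labelled 8 months, replicate 1, and 12 months, replicate 2, they were 4, 65, 71, 68, 23 and 73. Without the library labelled 8 months, replicate 2, and both 12-month libraries they were 4 for AbemaR, 18 for 8 months and 20 for 8 months against AbemaR.

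The replicate numbers gave no clear sign of pairing: of 12 same-numbered pairs, 2 correlated above 0.1 in their deviations from the group means, with a range of −0.267 to 0.211. Deviations within a group of 2 libraries mirror each other, so the same-numbered pairs between such groups repeat the same value. An absence of pairing is therefore not shown. With replicate number as a block, 0 genes passed in each comparison by edgeR, 0 calls were shared, and the smallest adjusted p were 0.298 for AbemaR and 0.11 for 12 months against parental cells. In that block fit the estrogen receptor list at 8 months had a median of 0.30, with the camera direction turned down. The block also ended the list calls of estrogen receptor targets and cholesterol biosynthesis in AbemaR (adjusted p = 0.238 and 0.0817), immediate-early genes and histones at 8 months (0.0723 and 0.057) and integrated stress for 12 against 8 months (0.078), and homologous recombination at 12 months newly passed (0.0408).

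Directions changed for these results, given with their lowest and highest log2 change when each library was left out in turn. A gene was judged by the sign of its log2 change and a list by its camera direction. The integrated stress list for 12 against 8 months is therefore not among them. Its median was −0.05 without 12-month replicate 1, but its camera direction stayed the same. In AbemaR against parental cells, PGR, at −0.06, ranged from −0.36 to 0.13 and was also at 0.12 without parental replicate 1 or 2. RB1, at −0.12, ranged from −2.61 without AbemaR replicate 2 to 0.73 without AbemaR replicate 1 and was at 0.03 without parental replicate 2. GREB1, at 0.29, ranged from −0.70 without AbemaR replicate 2 to 0.86 without AbemaR replicate 1. The estrogen receptor list ranged from a median of 0.00 to 0.81, the lower without AbemaR replicate 2, and the cholesterol list from −0.08 without AbemaR replicate 2 to 0.98 without AbemaR replicate 1. At 8 months against parental cells, PGR ranged from −1.01 to 3.12, RB1 from −0.05 to 1.55 and the estrogen receptor list from −0.22 to 0.78, the lowest each without 8-month replicate 2. With the 12-month libraries also left out these were −1.0, −0.04 and −0.22, and without parental replicate 3 the list's median was 0.36 with the camera direction down. At 12 months against parental cells, GREB1 ranged from −7.04 to 0.13, PGR from −5.02 to 2.20 and the estrogen receptor list from −2.61 to 0.35. The negative ends lay without 12-month replicate 1 and the positive ends without replicate 2. GREB1 and the list were again at 0.13 and 0.35 without 8-month replicate 1 and 12-month replicate 2. For 12 against 8 months, leaving out 12-month replicate 1 gave MUC19 6.76, GREB1 −6.87, PGR −7.21, the estrogen receptor list −2.05 and the interferon list −2.23. Leaving out 12-month replicate 2 gave MUC19 −0.85, GREB1 0.30, PGR 0.01 and the estrogen receptor list 0.02. Without 8-month replicate 1 as well, MUC19 was at −0.68, TFF1 at 0.03, GREB1 at 0.94, the estrogen receptor list at 0.27 and the interferon list at 0.73, where it passed as higher (adjusted p = 4.24e-06). PGR was at 2.07 without 8-month replicate 2, and the interferon list at 0.14 without 8-month replicate 1. For 8 months against AbemaR, PGR ranged from −0.95 without 8-month replicate 2 to 3.19 without replicate 1, and was at −0.93 with replicate 2 and the 12-month libraries left out. The integrated stress list of that comparison ranged from −1.64 without AbemaR replicate 2 to 0.31 without AbemaR replicate 1, and the mitosis list from −0.83 without AbemaR replicate 1 to 0.10 without AbemaR replicate 2.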

Other observations

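All tests in this part were chosen only after the results were seen, except the GC content and length test and the measurement of regional runs, which were planned.

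With the 12-month technical replicates summed to 1 sample, all 5 treated samples lay above all 3 parental samples for 1109 of 18988 genes and below for 758. Chance over the 56 splits of 8 exchangeable samples gives 1.79% each way, or 339 genes. These samples are not exchangeable. The library labelled 8 months, replicate 2, correlated at 0.981 with 12-month replicate 1, and AbemaR replicate 2 at 0.975 with the library labelled 8 months, replicate 1. That share is therefore no firm reference for the counts here. The share was highest among the mitosis genes, 38 of 40 above, and 31 of 46 replication genes, 12 of 35 replication stress genes and 19 of 33 interferon genes also lay above. So did 15 of 30 homologous recombination genes and 11 of 24 CDK-RB genes, with 1 below in each of these lists. Of the p53 targets, 19 of 27 lay below. BRCA2 was at 80.3 to 85.6 CPM in both AbemaR libraries and the library labelled 8 months, replicate 1, and at 17.3 to 22.9 in the library labelled 8 months, replicate 2, and both 12-month libraries, against 12.3 to 16.6 in the parental libraries. Genes read only in these last 3 treated libraries, above 8 CPM against under 0.3 in each of the other 6, numbered 45, and 29 were silent only in them. Among the 45, AGR3, a member of the estrogen receptor target list, was at 26.3 to 174 CPM. In the same 3 libraries TBX2, a transcription factor gene on chromosome 17, was at 0.449 to 1.79 CPM against 123 to 180 in the other 6, and ZIC1 was at 0 against 14.1 to 45.4, all 3 genes named after their values were seen.

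The library labelled 8 months, replicate 2, and both 12-month libraries stood apart from the other 6. At 12 months 67 runs of neighbouring genes lay beyond the limit of random orders, so the changes grouped by position. These runs cannot decide whether a gene-by-gene drug response on an unchanged genome was the whole cause. Random orders take no account of neighbours that are regulated together. Such runs also appeared at 8 months with replicate 2 left out, although the remaining 8-month library did not stand apart. A mixture in the library labelled 8 months, replicate 2, with cells like replicate 1 is argued against: 77 genes on in replicate 1 and silent in both 12-month libraries had a median level in replicate 2 of 0.273% of that in replicate 1. Cells of another culture or wrongly labelled libraries cannot be told apart here from a minority of the parental cells that grew out under the drugs. MTAP, a gene of chromosome 9 named after its values were seen, was at 31.2 to 41.8 CPM in these 3 libraries. Its highest parental level was 1.49% of the lowest of them. The MTAP test could not decide this, because the level set for another culture lay below that of 1 read in a parental library. The few parental reads neither show nor exclude such a minority. Selection by the drugs, the biological explanation the design offers, stays open and untested. Differences between these 3 libraries and the parental cells therefore cannot be assigned to the drugs.

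The 12-month libraries, technical replicates per the labels, differed from each other. Sampling of reads is argued against by a chi-square of 187 per degree of freedom, although no pair of libraries came below 51.5. A bias by GC content and length is argued against because its trend removed 2.93% of the variance of the log2 difference and left 1521 of 1579 genes over 2-fold apart. Preparation noise between libraries of one RNA is argued against by 10 genes silent in one library and at 50 CPM or more in the other, among them LHX9 and COL3A1 (on in replicate 2) and CLDN3 and TIMP1 (silent in it), all 4 named after their values were seen, where parental pairs had 0. No biological explanation was tested, as the labels give both libraries the same treatment and time.

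RB1, the target of CDK4 and CDK6 on chromosome 13 (48303726 to 48599436), was low in AbemaR replicate 1. Counting noise is argued against: its 60 reads gave 4.38 CPM with an exact 95% Poisson interval of 3.34 to 5.63, under the lowest parental value of 22.4. The 20 nearest tested genes (46052806 to 49495003) had a median difference of −0.73 in log2(CPM + 1) from the parental mean. Of these, 16 were lower, and the median lay at percentile 0.265 of 14741 such runs in this library. In AbemaR replicate 2 it lay at percentile 75.4. A shift of the whole neighbourhood, such as loss of 1 copy in this culture, may therefore be part of the cause, as a hypothesis found and tested on the same data. RB1 itself was at −2.36, below its neighbours, and selection by abemaciclib stays open and untested.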
